A study of Mus musculus with 57 samples.

How the data were processed

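RNA of mouse spleen, thymus, whole bone marrow and lineage-negative bone marrow (marrow depleted of mature blood cells) was measured on Affymetrix mouse expression arrays. RNA was extracted with Trizol, and 100 ng was reverse transcribed and labelled with biotin, per the labels' protocols. The deposited table held log2 signals made by the authors with RMA, per the submitters' processing notes; no version was given. It covered 44943 probe sets on 57 arrays, with values from 2.58 to 14.65 and array medians from 5.44 to 5.85. An aligner and a genome build are not given in the sources used here, and none is needed for these values. The number of arrays limits the precision of every comparison.

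Probe sets were joined to genes with the probe annotation supplied with the series. Of the probe sets, 64 were controls, 34842 named 1 gene, 931 named several and 9106 named none; only those with 1 gene were used. Each of the 18165 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 8980 genes with more than 1 probe set. Genes whose probe set lay above the 40th percentile of its array on at least 3 arrays were tested, which left 15314.

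Arrays were grouped by genotype, tissue and clinical state as labelled, which gave 14 groups. The 3 wild-type marrows labelled C57B6 formed a group apart from the other 6, whose strain is not in the labels. For each tissue, 1 limma model (limma 3.58.1 in R 4.3.3, lmFit and eBayes with default settings) held the mean of each group with no other term. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Errors printed beside log2 changes are the model's standard errors. Differences of a transgene's effect between tissues were tested with limma's moderated F test over all 57 arrays.

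There were 30 fixed gene lists: the HOXA, HOXB, HOXC and HOXD clusters, HOX cofactors, fusion partner genes, HOX-linked leukemia genes, stem and progenitor markers, T cell markers, immature thymocyte markers, B cell markers, B cell precursor markers, myeloid primary granule genes, neutrophil late granule genes, monocyte and macrophage markers, red pulp macrophage genes, erythroid genes, megakaryocyte and platelet genes, NK and cytotoxic genes, mast cell, basophil and eosinophil genes, dendritic cell genes, MHC class II genes, stromal and vessel genes, thymic epithelium genes, exocrine pancreas genes, mitotic genes, DNA replication genes, interferon response genes, immediate early genes, and Y-linked genes with Xist. Lists with at least 4 measured genes, 28 in all, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated per list. Members past the threshold were counted over all genes and adjusted over the list alone. Lists named for a cell type describe the cell mixture of bulk tissue, and no cell type was assigned to a sample from them.

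The named genes were chosen by a rule. It took, per comparison, up to 6 rises and 6 falls with the largest log2 change among called genes whose groups did not overlap on any array, leaving out predicted and clone symbols. It added Hoxa5, Hoxa7, Hoxa9, Hoxa10, Meis1 and Pbx3 in every comparison, up to 4 members with the smallest adjusted p of each list that passed, the fusion partners Mllt10, Nup98 and Hoxd13, and the sex-linked genes. For the F tests it took the 6 genes with the smallest p. The comparisons, models, gene lists, naming rule and a first set of alternatives were fixed before the data were examined.

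Equal replicate numbers are not said by the labels to mark 1 mouse, litter or day. Group-centred values of arrays with the same number were correlated across genes. In the 3 comparisons of lineage-negative marrow every pair correlated, from 0.20 to 0.70, 0.21 to 0.74 and 0.22 to 0.76, so values with the replicate number as a block stand beside those results where they changed a call. In each of these comparisons 2 of 3 arrays correlated best with their own number. The third arrays of the lineage-negative groups were also the ones with a narrow spread of values, described with the data.

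The alternatives tried were no filter and a filter at the 60th percentile, the mean of all probe sets of a gene, quantile normalization, a model of only the groups compared, a model of all arrays, eBayes with trend and robust settings, the replicate block, each array left out, and other control marrows. After the data were seen, further alternatives were added for the array sets, for 3 thymuses that stood apart, for RNA quality and for the C57B6 marrow difference. The models were tested on simulated data. With 100 genes each, a log2 change of 1 was recovered for 74 percent of genes in CA10 leukemic against CA10 healthy spleen and for 7 percent in CA10 against wild-type lineage-negative marrow. A change of 2 was recovered for 97 percent and 58 percent in these comparisons. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The strain of most mice, ages and sort gates are not in the labels and were not used here.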

Results

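Gene expression was measured on 57 arrays of hematopoietic tissue from mice with 1 of 2 leukemia transgenes and from wild-type mice. CA10 mice carry the CALM-AF10 fusion gene under the vav promoter, and NHD13 mice carry a fusion of NUP98 and HOXD13. Spleen was taken from CA10 mice with leukemia (6 arrays), NHD13 mice with leukemia (6), CA10 mice without clinical signs (5) and wild-type mice (2). Tissue of transgenic mice without clinical signs made up the remaining transgenic groups. Lineage-negative marrow came from CA10, NHD13 and wild-type mice (3 arrays each). Whole marrow came from CA10 (3), NHD13 (3), wild-type (6) and wild-type C57B6 mice (3), and thymus from CA10 (4), NHD13 (3) and wild-type mice (7). The labels do not say that each array is a separate mouse, so the p-values measure only the spread between these arrays.

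The levels of Xist and the Y-linked gene Eif2s3y separated 37 male from 20 female arrays, and the sexes were mixed in most groups. All 3 NHD13 lineage-negative marrows and all 3 C57B6 marrows were male. In CA10 against wild-type lineage-negative marrow the list of Y-linked genes with Xist rose (4 genes tested, camera adjusted p = 0.0294), with 2 of 3 CA10 arrays and 1 of 3 wild-type arrays male. Its adjusted p was 0.19 with an estimated correlation. In 10 arrays the 75th percentile of all signals was lower, from 6.90 to 7.15, against 7.26 to 7.72 in the other 47. This narrow set held all 3 CA10 whole marrows, wild-type whole marrows 4 to 6, the third array of each lineage-negative group and wild-type thymus 6. Wild-type whole marrows 4 to 6 were female and 1 to 3 male, so array set and sex cannot be told apart within these 6 arrays. The 3' minus 5' signal of Gapdh, a measure of RNA degradation, reached 2.95 in NHD13 lineage-negative marrow 3 and 2.09 in CA10 healthy spleen 1.

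The series asks how leukemic tissue, and tissue of transgenic mice without clinical signs, differs from wild-type tissue. Hoxa9, a homeobox gene of blood progenitors whose forced expression promotes leukemia, had a mean signal of 4.11 ± 0.22 (SD, n = 2) in wild-type spleen. It was 9.31 ± 1.05 (n = 6) in CA10 leukemic spleen, 9.19 ± 1.02 (n = 6) in NHD13 leukemic spleen and 8.57 ± 0.77 (n = 5) in CA10 spleen without clinical signs. On the other Hoxa9 probe set these means were 6.55 ± 0.28 in wild type, then 7.45 ± 0.78, 7.26 ± 0.39 and 7.03 ± 0.34. The size of the Hoxa9 rise thus depends on the probe set. Meis1, a HOX cofactor, was at 8.62 ± 1.06 (n = 6) in CA10 and 6.65 ± 1.48 (n = 6) in NHD13 leukemic spleen. Pbx3, another HOX cofactor, was at 10.91 ± 0.38 (n = 6) in NHD13 and 6.35 ± 1.66 (n = 6) in CA10 leukemic spleen.

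**Figure D1:**
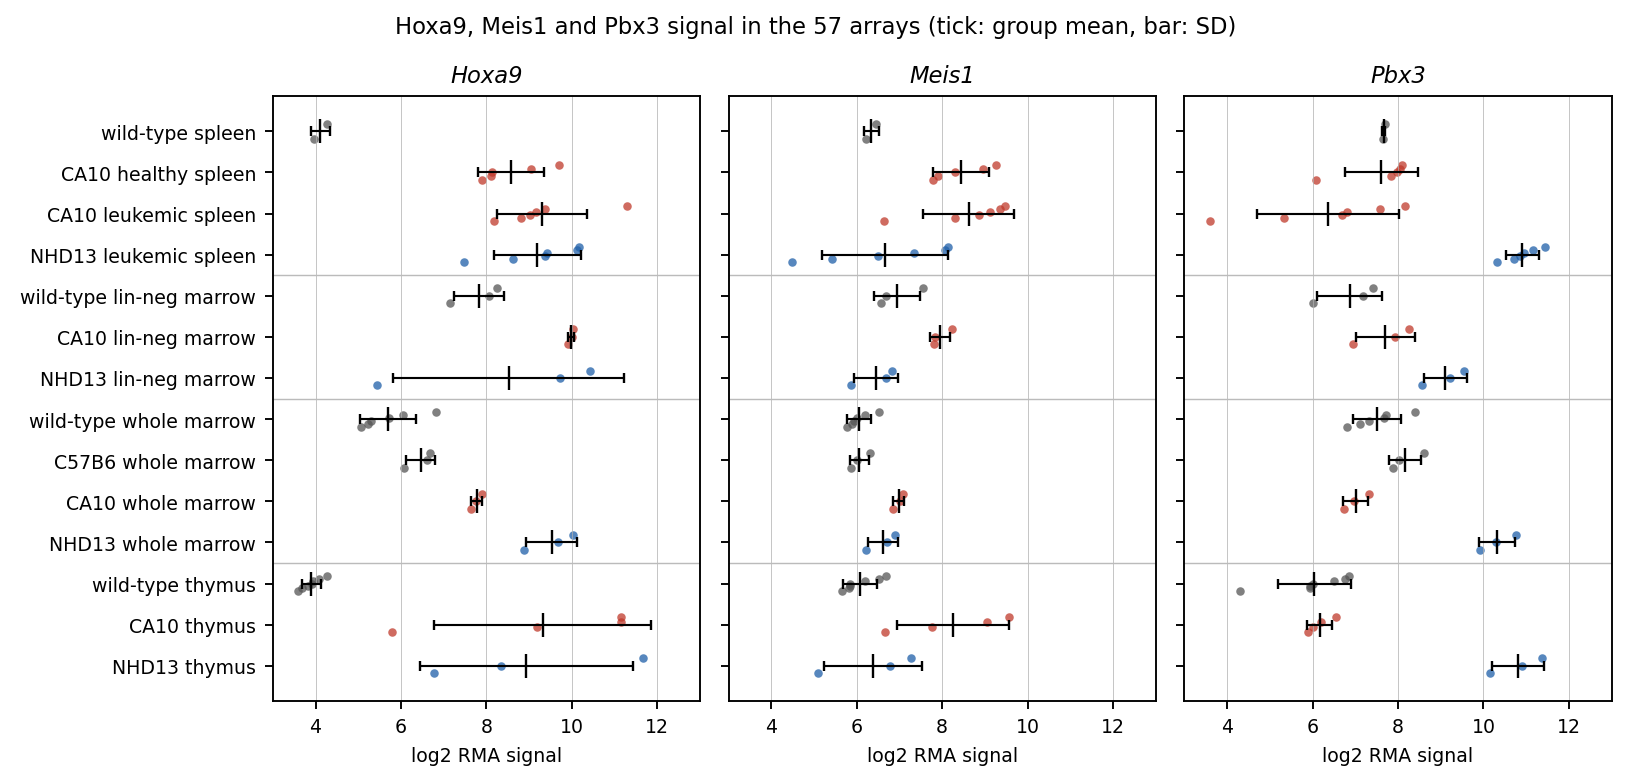
Log2 RMA signal (x axis) of Hoxa9, Meis1 and Pbx3 in each of 14 groups (y axis), with 1 point per array, a tick at the group mean and a bar for the SD (gray, wild type, red, CA10, blue, NHD13). In NHD13 tissues the mean of Pbx3 lies at 9.11 or higher, and in the other groups at 8.18 or lower.

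CA10 leukemic spleen was compared with spleen of CA10 mice without clinical signs. Ifi202b, an interferon-inducible gene, rose by 2.94 ± 0.43 log2 units (SE, n = 6 and 5, adjusted p = 0.00274). Klrk1, which encodes the activating receptor NKG2D, rose by 2.17 ± 0.38, and Cysltr1, a leukotriene receptor gene, by 2.13 ± 0.51 (adjusted p = 0.00669 and 0.0257). Fdps, an enzyme gene of sterol synthesis, rose by 1.79 ± 0.25, Clec4a3 by 1.69 ± 0.43 and Gna15 by 1.63 ± 0.30. Pxdc1 (−2.13 ± 0.39) and Bcl11b, a transcription factor gene of T cells (−1.90 ± 0.43), fell (adjusted p = 0.00825 and 0.0208). Trim2 (−1.55 ± 0.34), Dock9 (−1.43 ± 0.36), Als2cl (−1.33 ± 0.33) and Zbtb20 (−1.30 ± 0.36) fell as well. By the naming rule these 12 genes were taken from called genes whose groups did not overlap, which were 471 of the 920 called.

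Here and below, a change of a cell type's list in bulk tissue may be a changed share of cells, which was not tested. B cell markers fell in CA10 leukemic against CA10 healthy spleen (median −1.89, camera adjusted p = 1.3e-10). Of 18 genes 6 fell, and 15 did when adjusted over the list alone, among them Cr2, a complement receptor gene (−3.09 ± 0.80), and Blk, a kinase gene of B cells (−2.56 ± 0.58). T cell markers fell (2 of 17 genes, 2 adjusted over the list alone, camera adjusted p = 0.000283), Cd4 among them (adjusted p = 0.00967). Immature thymocyte markers (2 of 12, 3 over the list alone, adjusted p = 0.00935) and B cell precursor markers (2 of 12 both ways, adjusted p = 0.00968) fell as lists. So did erythroid genes (0 of 19, adjusted p = 0.000872), HOX cofactors (0 of 8, 1 over the list alone, adjusted p = 0.0399) and stromal and vessel genes (1 of 17, adjusted p = 0.0399). Monocyte and macrophage markers rose (2 of 17 genes, 7 adjusted over the list alone, adjusted p = 0.000444), with Cx3cr1 at 1.60 ± 0.41 and Cd68 at 1.40 ± 0.37. Myeloid primary granule genes (0 of 9, 1 over the list alone, adjusted p = 0.00742), neutrophil late granule genes (0 of 15, adjusted p = 0.0309) and interferon response genes (0 of 17, adjusted p = 0.00968) also rose as lists. With an estimated correlation the adjusted p of these 11 lists lay between 0.355 for the HOX cofactors and 0.884 for the neutrophil genes. With the Gapdh 3' minus 5' signal as a covariate 913 genes were called and the HOX cofactor list did not pass. Clec4a3, Dock9, Zbtb20, Cd68, Notch3 and Nup98 were then not called, while Ctsg (4.51), F13a1 (4.03), Ms4a3, Prtn3, Mx1, Fcgr1 and Cecr2 were.

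Hoxa9 stood at 0.73 ± 0.52, Hoxa10 at 0.97 ± 0.44, Hoxa7 at 0.23 ± 0.24, Hoxa5 at −0.10 ± 0.21, Meis1 at 0.18 ± 0.62 and Pbx3 at −1.25 ± 0.60 in this comparison, none of them called (adjusted p from 0.201 to 0.908). Another Meis1 probe set was at 8.77 ± 0.56 (SD) in CA10 leukemic and 7.80 ± 0.76 in CA10 healthy spleen. A weaker Meis1 probe set was at 4.76 ± 0.15 and 4.57 ± 0.28. The other Pbx3 probe set was at 6.17 ± 0.45 and 6.32 ± 0.42, so the size of both changes depends on the probe set. In all, limma called 920 genes, 640 higher and 280 lower. The count moved with single arrays: it was 1413, 588, 503 and 127 without CA10 healthy 1, 2, 4 and 5, and 469, 510, 274 and 378 without CA10 leukemic 1, 2, 3 and 6.

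Against wild-type spleen, CA10 leukemic spleen had Hoxa9 higher by 5.19 ± 0.71 log2 units (SE, n = 6 and 2, adjusted p = 0.00329). Ctsg, the gene of the granule protease cathepsin G, rose by 5.13 ± 1.30, Bex6 by 4.38 ± 1.26, F13a1, a coagulation factor gene of monocytes, by 4.34 ± 1.09, Ifi202b by 4.23 ± 0.58 and the chemokine gene Ccl9 by 4.17 ± 0.99. Cr2 (−4.30 ± 1.08), Srpk3 (−4.14 ± 0.86), Blk (−3.72 ± 0.78), Cd79a, part of the B cell receptor (−3.60 ± 1.00), Dtx1 (−3.57 ± 0.74) and Cxcl13, a chemokine gene of B cell follicles (−3.41 ± 0.85), fell. These largest rises and falls were taken by rule from called genes whose groups did not overlap, 1232 of the 1242 called. Meis1 at 2.28 ± 0.83, Hoxa10 at 1.64 ± 0.59, Hoxa7 at 0.71 ± 0.32, Hoxa5 at 0.10 ± 0.28 and Pbx3 at −1.31 ± 0.81 were not called. Another Meis1 probe set was at 8.77 ± 0.56 (SD) in CA10 leukemic and 5.71 ± 0.34 in wild-type spleen, and a weaker one at 4.76 ± 0.15 and 4.44 ± 0.01. The other Pbx3 probe set was at 6.17 ± 0.45 and 6.73 ± 0.26.

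In this comparison B cell markers fell (9 of 18 genes, 18 adjusted over the list alone, median −2.90, camera adjusted p = 2.25e-12) and so did T cell markers (3 of 17, 9 over the list alone, adjusted p = 1.16e-06). Erythroid genes (0 of 19, adjusted p = 0.000862) and stromal and vessel genes (1 of 17, adjusted p = 0.00664) fell as lists. Myeloid primary granule genes rose (2 of 9, 6 adjusted over the list alone, median 3.37, adjusted p = 0.000849). Myb stood at 1.95 ± 0.54. Monocyte and macrophage markers (4 of 17, 7 over the list alone, adjusted p = 0.000856) and neutrophil late granule genes (0 of 15, 2 over the list alone, adjusted p = 0.00386) rose too. These lists had adjusted p = 0.539 or 0.773 with an estimated correlation. limma called 1242 genes, 869 higher and 373 lower. The count was 1 without wild-type spleen 1, 0 without wild-type spleen 2 and 719 without CA10 leukemic 3.

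NHD13 leukemic spleen against wild-type spleen had the largest rises in Stfa2l1 (6.31 ± 1.51 log2 units, SE, n = 6 and 2, adjusted p = 0.00455) and Stfa3 (6.00 ± 1.73), genes of stefin protease inhibitors. Hoxa9 rose by 5.08 ± 0.71 (adjusted p = 0.000105), Ctsg by 5.08 ± 1.30, Ms4a3, a gene of granulocyte and monocyte progenitors, by 5.03 ± 1.35 and Mfsd13a by 5.00 ± 0.99. Pbx3 rose by 3.24 ± 0.81 and Hoxa7 by 1.44 ± 0.32 (adjusted p = 0.00608 and 0.00269). Hoxa10 at 0.82 ± 0.59, Hoxa5 at 0.33 ± 0.28 and Meis1 at 0.32 ± 0.83 were not called, though Hoxa5 was called at 1.41 with the mean of its probe sets. Serpina1b (−7.60 ± 0.57), Cd79a (−7.45 ± 1.00), the antibody gene segment Ighv14-2 (−7.30 ± 0.92), Cr2 (−6.94 ± 1.08), Ms4a1, which encodes CD20 (−6.71 ± 1.19), and Srpk3 (−5.88 ± 0.86) fell. The largest rises and falls were again taken from called genes whose groups did not overlap, 4453 of the 4803 called.

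All 18 B cell markers fell in NHD13 leukemic spleen, over all genes and adjusted over the list alone (median −5.10, camera adjusted p = 6.41e-14). MHC class II genes, which present antigen, fell (7 of 9, 8 adjusted over the list alone, adjusted p = 1.92e-07), with Cd74 at −5.06 ± 0.44 and H2-Aa at −5.22 ± 0.56. T cell markers fell (13 of 17 lower and 1 higher, both ways, adjusted p = 5.98e-07), with Cd4 at −2.64 ± 0.26. B cell precursor markers (6 of 12 lower and 1 higher, adjusted p = 0.0271), dendritic cell genes (4 of 12 lower, adjusted p = 0.00769) and NK and cytotoxic genes (5 of 13 lower and 1 higher, 6 and 1 over the list alone, adjusted p = 0.0433) fell as lists. Myeloid primary granule genes (6 of 9, adjusted p = 0.0087), neutrophil late granule genes (5 of 15, adjusted p = 0.0222), mitotic genes (8 of 19, 14 adjusted over the list alone, adjusted p = 0.000212) and DNA replication genes (11 of 20, adjusted p = 0.00702) rose. Kif20a, a motor gene of cell division, stood at 2.38 ± 0.45 and Cdc45, a replication helicase gene, at 1.87 ± 0.39. Their adjusted p was 0.273 to 0.721 with an estimated correlation.

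limma called 4803 genes in NHD13 leukemic against wild-type spleen, 2919 higher and 1884 lower. Without wild-type spleen 1 or 2 the count was 2374 or 2149. The NHD13 leukemic arrays shared levels of labelling controls with the C57B6 marrows, and lay on their side for most genes that set those marrows apart. With the C57B6 marrow difference subtracted, an alternative chosen after seeing the data, 2512 genes were called, 1877 of them in both. Hoxa9 then stood at 4.32, Pbx3 at 2.57, Hoxa7 at 1.80 and Cd79a at −5.65, all still called, whereas Stfa2l1 (3.97), Stfa3 (4.08), Ifitm6, Chil3, Cd3d and Cplx2 were no longer called. The HOXA and HOXC clusters rose as lists with this subtraction, and immature thymocyte, red pulp macrophage, interferon response and immediate early genes fell. All spleens and C57B6 marrows were in the wide array set and wild-type marrows 4 to 6 in the narrow one, so array-set differences enter this subtraction. Hoxa5 was at 6.53 to 6.79 in wild-type marrows 1 to 3 and at 7.97 to 8.30 in 4 to 6. Hoxa7 was at 6.47 to 6.89 and 7.38 to 7.74, so its value of 1.80 and the HOXA list are affected.

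**Figure D2:**
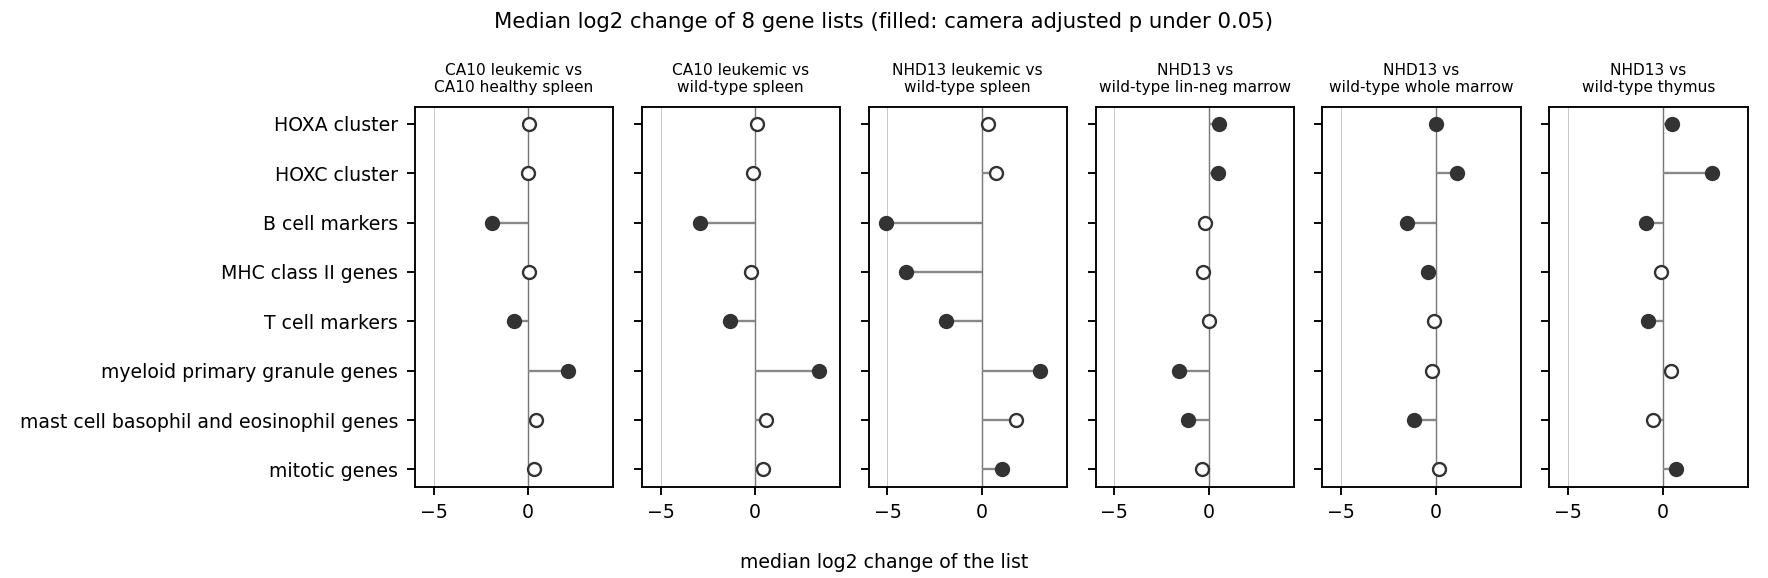
Median log2 change (x axis) of 8 gene lists (y axis) in 6 comparisons, with filled points where camera passed at its preset correlation and open points where it did not. B cell markers lie at −5.10 in NHD13 leukemic spleen, −2.90 in CA10 leukemic spleen and −1.50 in NHD13 whole marrow.

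The leukemias of the transgenes were compared directly in spleen (n = 6 and 6). CA10 leukemic spleen had Ifi202b higher by 6.80 ± 0.41 log2 units (SE, adjusted p = 7.51e-09), Serpina1b by 6.20 ± 0.40, H2-Aa by 5.04 ± 0.40, Cd74 by 4.78 ± 0.31, H2-Ab1 by 4.34 ± 0.35 and Gdpd3 by 4.26 ± 0.48. Pbx3 (−4.55 ± 0.58, adjusted p = 3.28e-05), Ms4a4b (−4.32 ± 0.48), Klhl4 (−3.50 ± 0.49), Hoxc4, a homeobox gene (−3.49 ± 0.36), Mndal, an interferon-inducible gene (−3.37 ± 0.27), and Ang, the gene of angiogenin (−3.37 ± 0.21), were lower. These 12 genes were chosen from called genes whose groups did not overlap, which were 1570 of the 3782 called. Meis1 was higher in CA10 by 1.97 ± 0.59 (adjusted p = 0.0217) and Hoxa7 was lower (−0.73 ± 0.22, adjusted p = 0.0257). Hoxa9 at 0.11 ± 0.50, Hoxa10 at 0.82 ± 0.42 and Hoxa5 at −0.24 ± 0.20 were not called.

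In CA10 against NHD13 leukemic spleen MHC class II genes were higher (8 of 9, median 3.38, camera adjusted p = 6.66e-10). Dendritic cell genes were higher (9 of 12, 10 adjusted over the list alone, median 2.46, adjusted p = 1.6e-06), with Cd209a at 4.12 ± 0.63 and Itgax, which encodes CD11c, at 3.28 ± 0.47. The dendritic cell list also passed with an estimated correlation (adjusted p = 0.0226). B cell markers (12 of 18, 15 over the list alone, adjusted p = 4.07e-07), T cell markers (7 of 17 higher and 1 lower, adjusted p = 0.00579), and NK and cytotoxic genes (6 of 13 higher and 1 lower, 8 and 1 over the list alone, adjusted p = 0.00226) were higher. So were monocyte and macrophage markers (6 of 17, 7 over the list alone, adjusted p = 0.000351), interferon response genes (8 of 17, adjusted p = 6.34e-05) and immediate early genes (4 of 14, adjusted p = 0.0103). The HOXC cluster (4 of 5 lower, adjusted p = 0.00627), mitotic genes (7 of 19, 9 over the list alone, adjusted p = 0.000351), DNA replication genes (3 of 20, 1 over the list alone, adjusted p = 0.00627) and erythroid genes (0 of 19, adjusted p = 0.0277) were lower. The adjusted p of the other lists was 0.199 for MHC class II genes and between 0.455 and 0.733 for the rest with an estimated correlation.

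limma called 3782 genes, 1791 higher and 1991 lower in CA10 leukemic spleen. With the C57B6 marrow difference subtracted, 1452 were called, 803 of them in both. Pbx3 (−3.88), Hoxc4 (−3.30), Klhl4 (−3.50), Ifi202b (2.53) and Serpina1b (5.38) were still called. Meis1 (1.97), Hoxa7 (−1.09), Gdpd3 (1.46), Ang (−0.18), Cd79a (2.04) and Nup98 (−0.35) were not. Serpina1b was low in C57B6 and other wild-type marrow (3.87 and 4.70), so this subtraction could not remove a strain effect on it in spleen. Ifi202b had a mean of 4.31 in both NHD13 leukemic spleen and C57B6 marrow. Its value of 2.53 thus sets CA10 leukemic spleen (11.12) against other wild-type marrow (8.58), and does not show a difference between the leukemias beyond strain. The subtracted values of Ms4a4b (1.68) and Mndal (1.76) turned positive. Their signals were still lower in CA10 leukemic spleen, at 3.69 ± 0.10 and 4.33 ± 0.26 (SD, n = 6). In NHD13 leukemic spleen they were 8.01 ± 1.53 and 7.69 ± 0.79 (n = 6). C57B6 marrow lay higher still, at means of 9.67 and 8.65, so the turned sign comes from the subtraction. B cell precursor markers were higher, and megakaryocyte and stromal genes lower, with this subtraction, into which array-set differences of wild-type marrow enter as well.

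The C57B6 marrows, compared with the 6 other wild-type marrows, differed from them in many genes; whether by strain or by a separate labelling of these arrays cannot be told apart. Ms4a4b was higher by 6.00 ± 0.20 log2 units (SE, n = 3 and 6, adjusted p = 4.71e-12), H2-Q10, an MHC class I gene, by 5.15 ± 0.21, Mndal by 5.12 ± 0.16, Trim30d by 4.71 ± 0.27, H2-Eb1, an MHC class II gene, by 3.93 ± 0.28 and Mir1931 by 3.76 ± 0.14. Ptp4a2 (−4.96 ± 0.41), Ifi202b (−4.27 ± 0.39), Zfp207 (−3.35 ± 0.39) and Psmb7, a proteasome gene (−2.86 ± 0.16), were lower. Hoxa9 stood at 0.76 ± 0.33, Hoxa10 at −0.08 ± 0.18, Hoxa7 at −0.37 ± 0.29, Hoxa5 at −0.93 ± 0.35, Meis1 at 0.01 ± 0.19 and Pbx3 at 0.68 ± 0.29, none called. limma called 2946 genes, 2150 higher and 796 lower, and the count was 1613, 1928 and 1534 without C57B6 marrow 1, 2 and 3.

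Of the lists in C57B6 against other wild-type marrow, DNA replication genes were lower (11 of 20, 14 adjusted over the list alone, camera adjusted p = 3.52e-08) and erythroid genes were lower (8 of 19, 9 over the list alone, adjusted p = 3.77e-05). B cell markers (10 of 18, adjusted p = 0.000408), MHC class II genes (6 of 9, adjusted p = 0.00131) and mast cell, basophil and eosinophil genes (6 of 11, adjusted p = 0.00629) were higher, each with 1 gene lower. Over the list alone 11, 7 and 7 were higher and 1, 1 and 2 lower. In all 13 lists passed, and their adjusted p with an estimated correlation lay between 0.288 and 0.691. The monocyte and exocrine pancreas lists did not pass within the wide array set, where stem and progenitor and myeloid primary granule genes were lower. In the NHD13 leukemic spleens, 75.6 percent of 84 genes that differed by at least 2 log2 units between these marrows lay on the C57B6 side (median of 6 arrays, range 56.0 to 92.9), against at most 33.3 percent in the 48 arrays of the other groups.

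**Figure D3:**
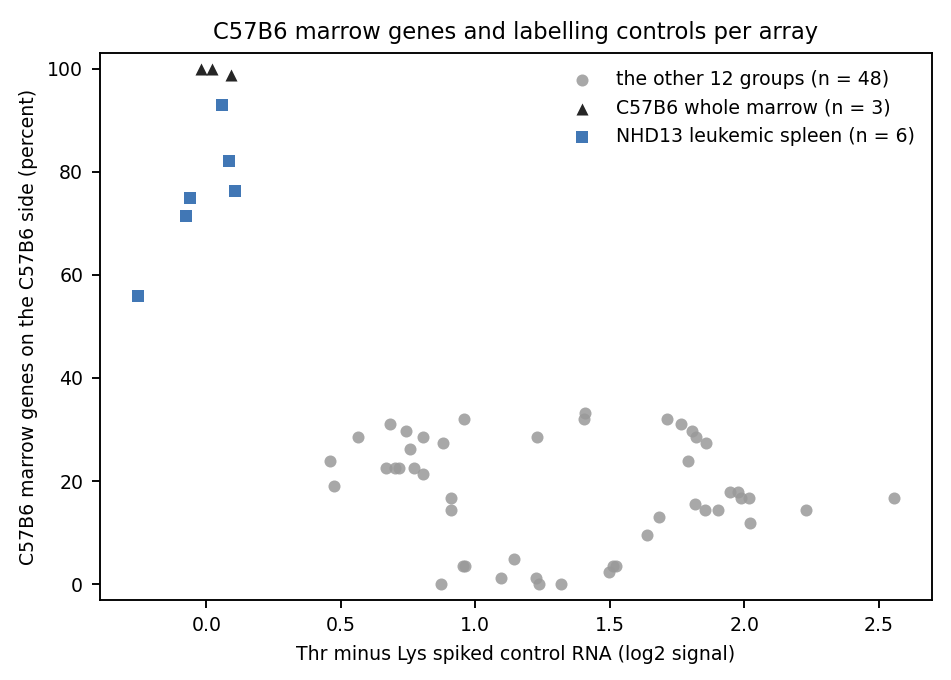
Share of the 84 genes that set the C57B6 marrows apart lying on the C57B6 side (y axis, percent) against the log2 signal difference of the spiked control RNAs Thr and Lys (x axis), 1 point per array. The 3 C57B6 marrows and 6 NHD13 leukemic spleens lie at −0.26 to 0.11 on the x axis, and the other 48 arrays at 0.46 to 2.56.

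CA10 spleen without clinical signs was compared with wild-type spleen (n = 5 and 2). Hoxa9 stood at 4.46 ± 0.72 log2 units (SE, adjusted p = 0.134), with all 5 CA10 arrays above both wild-type arrays, and Meis1 at 2.10 ± 0.85 (adjusted p = 1.0). Hoxa10 stood at 0.67 ± 0.60, Hoxa7 at 0.48 ± 0.32, Hoxa5 at 0.20 ± 0.28 and Pbx3 at −0.06 ± 0.83. As lists, the HOXA cluster rose (0 of 8 genes, 1 adjusted over the list alone, camera adjusted p = 0.00128). Myeloid primary granule genes (0 of 9, adjusted p = 0.00575) and neutrophil late granule genes (0 of 15, adjusted p = 0.021) rose too. T cell markers (0 of 17, adjusted p = 4.31e-05), B cell markers (0 of 18, adjusted p = 2.82e-06) and stromal and vessel genes (0 of 17, adjusted p = 0.0355) fell. With an estimated correlation the adjusted p was 0.869 for the HOXA cluster and 0.936 for the others. limma called 0 genes, with 388 at an unadjusted p under 0.05, and leaving out any 1 array gave 0 as well.

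In CA10 against wild-type lineage-negative marrow (n = 3 and 3) the HOXA cluster rose as a list (0 of 8 genes, 1 adjusted over the list alone, median 0.30, camera adjusted p = 2.26e-07), also with an estimated correlation (adjusted p = 0.033). Hoxa9 stood at 2.16 ± 1.05 log2 units, Hoxa10 at 2.06 ± 0.54, Meis1 at 1.01 ± 0.36, Pbx3 at 0.84 ± 0.47, Hoxa5 at 0.34 ± 0.30 and Hoxa7 at 0.27 ± 0.31, each with adjusted p = 1.0. Neutrophil late granule genes (adjusted p = 5.63e-16), B cell markers (adjusted p = 0.0055), the HOXB cluster (adjusted p = 0.0188), HOX cofactors (adjusted p = 0.0258) and erythroid genes (adjusted p = 0.0439) rose as lists, with S100a9, a neutrophil gene, at 2.46 ± 1.01. Myeloid primary granule genes (adjusted p = 3.09e-10), megakaryocyte and platelet genes (adjusted p = 2.64e-06), mast cell, basophil and eosinophil genes (adjusted p = 0.000174) and HOX-linked leukemia genes (adjusted p = 0.000314) fell as lists, with Mpo, the gene of myeloperoxidase, at −1.13 ± 0.41. No member of these 9 lists passed, over all genes or adjusted over the list alone. Their adjusted p was 0.19 to 0.82 with an estimated correlation. limma called 0 genes, with 71 at an unadjusted p under 0.05, and 0 with the replicate number as a block. In the blocked fit the HOXB, cofactor and erythroid lists each had adjusted p = 0.0533, within ranges of 0.00383 to 0.436, 0.0128 to 0.337 and 0.00142 to 0.995 over the alternatives. Within the wide array set the HOXB, cofactor, B cell and megakaryocyte lists did not pass, and with the array set as a block the cofactor list did not. NK and DNA replication genes rose within the wide set. Hoxa5 was at 1.02, not called, with the mean of its probe sets. The other Hoxa10 probe set did not rise, at 4.29 ± 0.51 (SD) in CA10 and 4.37 ± 0.27 in wild type. Nor did the other Pbx3 probe set beyond its spread, at 6.68 ± 0.56 in CA10 and 6.63 ± 0.20 in wild type.

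NHD13 lineage-negative marrow had lower levels of some myeloid primary granule genes and of a basophil gene than wild type (n = 3 and 3). Mcpt8, a basophil protease gene (−5.69 ± 0.65 log2 units, SE, adjusted p = 0.0218), Ctsg (−4.13 ± 0.47), Mpo (−3.64 ± 0.41), Cd34, a progenitor surface gene (−2.85 ± 0.37), and Irf8, a transcription factor gene of monocytes (−2.73 ± 0.35), fell, and so did Prtn3, a primary granule gene (adjusted p = 0.0293). For all 9 called genes the 3 NHD13 arrays lay below the 3 wild-type arrays. Pbx3 stood at 2.24 ± 0.47, Hoxa7 at 0.74 ± 0.31, Hoxa9 at 0.70 ± 1.05, Hoxa5 at 0.56 ± 0.30 and Meis1 at −0.48 ± 0.36, none called, and neither was Hoxa10 (adjusted p = 0.946). Hoxa9 was at 9.73 and 10.42 in NHD13 marrows 1 and 2 and at 5.43 in marrow 3, the array with degraded RNA, and without marrow 3 Hoxa9 stood at 2.25 and Hoxa10 at 2.14, both called. limma called 9 genes, all lower. The count was 15 with the replicate number as a block, 31 without NHD13 marrow 3 and 0 without NHD13 marrow 1, wild-type marrow 1 or wild-type marrow 3.

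Myeloid primary granule genes fell in NHD13 lineage-negative marrow (3 of 9, 7 adjusted over the list alone, camera adjusted p = 6.28e-18), as did mast cell, basophil and eosinophil genes (1 of 11, 6 over the list alone, adjusted p = 3.36e-06). HOX-linked leukemia genes (0 of 17, 2 over the list alone, adjusted p = 0.00193), megakaryocyte and platelet genes (0 of 11, 1 over the list alone, adjusted p = 0.00612), stem and progenitor markers (1 of 18, adjusted p = 0.0331) and monocyte and macrophage markers (1 of 17, adjusted p = 0.0331) fell as lists. The HOXA cluster (0 of 8, adjusted p = 0.0045) and the HOXC cluster (0 of 5, 1 over the list alone, adjusted p = 0.000194) rose, with Hoxc4 at 1.67 ± 0.39. The adjusted p of these lists was 0.187 to 0.604 with an estimated correlation. With the replicate block the monocyte list had adjusted p = 0.104, within 4.48e-07 to 0.736 over the alternatives. With the array set as a block the monocyte, megakaryocyte and stem and progenitor lists did not pass, and within the wide array set the stem and progenitor list did not. In that set, without the third arrays, erythroid genes and, with their direction turned, mitotic genes also rose, and B cell precursor markers and stromal genes fell. The Y-linked genes with Xist rose there too, with all NHD13 arrays male and the wild-type arrays of both sexes. Hoxa5 in this comparison was at 1.11, not called, with the mean of its probe sets, and Pbx3 was called with the block.

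Between CA10 and NHD13 lineage-negative marrow (n = 3 and 3) myeloid primary granule genes were higher in CA10 as a list (0 of 9, 4 adjusted over the list alone, camera adjusted p = 3.51e-12), with Ctsg at 3.00 ± 0.47 and Mpo at 2.52 ± 0.41, and the HOXC cluster was lower (0 of 5, 1 over the list alone, adjusted p = 0.00148). Mast cell, basophil and eosinophil genes (0 of 11, 5 over the list alone, adjusted p = 0.00148), DNA replication genes (adjusted p = 0.0178), neutrophil late granule genes (adjusted p = 0.0178), B cell precursor markers (adjusted p = 0.0178), monocyte and macrophage markers (0 of 17, 1 over the list alone, adjusted p = 0.0198) and B cell markers (adjusted p = 0.0208) were higher as lists, with no gene called where no count is given. The adjusted p was 0.491 for the primary granule genes and 0.73 for the others with an estimated correlation. Meis1 stood at 1.49 ± 0.36, Hoxa9 at 1.46 ± 1.05, Hoxa10 at 0.57 ± 0.54, Hoxa5 at −0.21 ± 0.30, Hoxa7 at −0.48 ± 0.31 and Pbx3 at −1.40 ± 0.47. limma called 0 genes, with 321 at an unadjusted p under 0.05; 1 was called with the replicate block and 5 without NHD13 marrow 3. In the blocked fit 5 lists no longer passed: mast cell (adjusted p = 0.0516), B cell precursor (0.0863), B cell (0.113), monocyte (0.113) and neutrophil genes (0.12). Over the alternatives the p of these lists ranged from 2.03e-08 to 0.73, 9.11e-06 to 0.736, 2.33e-06 to 0.736, 2.03e-08 to 0.784 and 3.1e-07 to 0.817. The direction of the DNA replication list turned: it was called lower in CA10 without NHD13 marrow 3, the array with degraded RNA, and did not pass within the wide array set. There, without the third arrays, erythroid and mitotic genes were called lower in CA10, with directions turned, and megakaryocyte, NK and stromal genes higher. Hoxa9 stood at −0.12 in that set.

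In whole marrow of CA10 against wild-type mice (n = 3 and 6) Hoxa9 stood at 2.07 ± 0.33 log2 units (adjusted p = 0.105), Meis1 at 0.93 ± 0.19, Hoxa10 at 0.92 ± 0.18, Hoxa5 at 0.80 ± 0.35, Hoxa7 at 0.28 ± 0.29 and Pbx3 at −0.49 ± 0.29. The HOXA cluster rose as a list (0 of 8, 2 adjusted over the list alone, camera adjusted p = 0.00143), as did thymic epithelium genes (0 of 11, 2 over the list alone, adjusted p = 0.0227), whose members include keratin genes such as Krt14 (0.65 ± 0.20). Megakaryocyte and platelet genes (0 of 11, 5 over the list alone, adjusted p = 0.000191), mitotic genes (0 of 19, adjusted p = 0.000684), erythroid genes (0 of 19, adjusted p = 0.00287) and DNA replication genes (0 of 20, 1 over the list alone, adjusted p = 0.0304) fell as lists. The adjusted p of these 6 lists was 0.728 to 0.886 with an estimated correlation. limma called 0 genes, with 2345 at an unadjusted p under 0.05.

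All 3 CA10 marrows belonged to the narrow array set, as did wild-type marrows 4 to 6. Within that set Hoxa9 rose by 2.57 and Meis1 by 1.12. Hoxa10 stood at 0.95, Hoxa5 at 0.05, Pbx3 at −0.06 and Hoxa7 at −0.21, the last with its direction turned, none called. There limma called 6 genes, and 1 with the array set as a block over all marrows, Hoxa9. In the pooled fit the count was 13 without wild-type marrow 5 and 1 without wild-type marrow 2. Within the narrow set and with the block the HOXA, thymic epithelium and DNA replication lists did not pass.

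NHD13 whole marrow had higher Hoxa9, by 3.83 ± 0.33 log2 units (SE, n = 3 and 6, adjusted p = 4.13e-06), Stfa3 by 4.52 ± 0.52, Klhl4 by 3.43 ± 0.23, Dach2 by 3.36 ± 0.27, Mmp13, a collagenase gene, by 3.00 ± 0.31 and Stfa2l1 by 2.98 ± 0.40 than wild type. Pbx3 rose by 2.82 ± 0.29 and Hoxa10 by 1.38 ± 0.18 (adjusted p = 3.44e-05 and 0.000516). The other Hoxa9 probe set differed less, at 7.81 ± 0.37 (SD) in NHD13 and 6.92 ± 0.54 in wild type. The other Hoxa10 probe set went the other way, at 3.75 ± 0.07 and 4.13 ± 0.40. Hoxa7 at 0.51 ± 0.29, Meis1 at 0.56 ± 0.19 and Hoxa5 at −0.16 ± 0.35 were not called. The sign of Hoxa5 depends on the probe set: the one used differed between wild-type marrows 1 to 3 (6.53 to 6.79) and 4 to 6 (7.97 to 8.30), which are the array sets, and the mean of probe sets gave 1.26, which was called. The eosinophil genes Ear3 (−5.89 ± 0.35), Prg2 (−3.71 ± 0.62) and Epx (−2.93 ± 0.49), the antibody gene Ighm (−3.26 ± 0.22), Mcpt8 (−2.97 ± 0.23) and Ms4a1 (−2.86 ± 0.38) fell. These largest rises and falls come by rule from called genes whose groups did not overlap, 172 of the 181 called.

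B cell markers fell in NHD13 whole marrow (13 of 18, 16 adjusted over the list alone, median −1.50, camera adjusted p = 1.75e-27), as did mast cell, basophil and eosinophil genes (6 of 11, 7 over the list alone, adjusted p = 4.18e-11), both also with an estimated correlation (adjusted p = 0.0134 and 0.00273). B cell precursor markers (4 of 12 lower and 1 higher, 8 and 1 over the list alone, adjusted p = 3.2e-05), MHC class II genes (2 of 9, 3 over the list alone, adjusted p = 0.000429), neutrophil late granule genes (0 of 15, adjusted p = 0.0077), dendritic cell genes (2 of 12, 4 lower and 2 higher over the list alone, adjusted p = 0.0391) and NK and cytotoxic genes (0 of 13, adjusted p = 0.0437) fell as lists. Megakaryocyte and platelet genes (1 of 11, 10 over the list alone, adjusted p = 3.07e-07), stromal and vessel genes (2 of 17 higher and 1 lower, 6 and 1 over the list alone, adjusted p = 0.0007), and interferon response genes (0 of 17, adjusted p = 0.0007) rose. The HOXC cluster (2 of 5, 3 over the list alone, adjusted p = 0.00169), DNA replication genes (0 of 20, adjusted p = 0.00516), stem and progenitor markers (2 of 18, 7 higher and 1 lower over the list alone, adjusted p = 0.00605) and the HOXA cluster (2 of 8, adjusted p = 0.0437) rose too. These other lists had an adjusted p of 0.207 or higher with an estimated correlation.

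limma called 181 genes in NHD13 against wild-type whole marrow, 93 higher and 88 lower. All 3 NHD13 marrows were in the wide array set, and with the array set as a block 355 genes were called, with Hoxa9 at 3.33, Pbx3 at 2.39, Hoxa7 at 1.00, Ear3 at −5.39, Ighm at −3.34 and Mcpt8 at −3.25 among them. The stem and progenitor list did not pass with the block, and within the wide set the stem and progenitor, DNA replication and interferon lists did not. In both of these fits myeloid primary granule genes fell. The count was 120 without NHD13 marrow 1, 93 without NHD13 marrow 2 and 278 without wild-type marrow 2.

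The 3 CA10 whole marrows were all in the narrow and the 3 NHD13 whole marrows all in the wide array set, so genotype and set can be parted only through the wild-type marrows in both. Those of the narrow set were female and those of the wide set male, so sex goes with the set there. In the pooled fit Ear3 was higher in CA10 by 5.72 ± 0.41 log2 units (SE, n = 3 and 3, adjusted p = 1.32e-06), Prg2 by 3.43 ± 0.72, Sbk1 by 2.95 ± 0.32, Epx by 2.84 ± 0.57, Fcer1a, an IgE receptor gene, by 2.65 ± 0.29 and Mcpt8 by 2.62 ± 0.27. Stfa3 (−3.77 ± 0.60), Klhl4 (−3.52 ± 0.26), Mageb16 (−3.46 ± 0.88), Mmp13 (−3.44 ± 0.36), Pbx3 (−3.31 ± 0.34), Dach2 (−3.18 ± 0.31) and Hoxa9 (−1.75 ± 0.38) were lower. Hoxa5 at 0.96 ± 0.41, Meis1 at 0.37 ± 0.22, Hoxa7 at −0.22 ± 0.34 and Hoxa10 at −0.45 ± 0.21 were not called. With the array set as a block Ear3 (4.73), Mcpt8 (3.19), Fcer1a (2.98), Sbk1 (2.99), Klhl4 (−3.41), Dach2 (−3.25), Mmp13 (−2.61) and Pbx3 (−2.45) were still called, and Hoxa9 (−0.75), Prg2 (2.18), Epx, Stfa3 (−2.96) and Mageb16 (−0.64) were not. Hoxa5 (−0.52), with its direction turned, and Hoxa7 (−1.21) were not called there either.

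limma called 4452 genes between CA10 and NHD13 whole marrow, 2192 higher and 2260 lower, and 147 with the array set as a block, 63 of them in both. The pooled count was 1693, 525 and 246 without CA10 marrow 1, 2 and 3, and 678, 124 and 2801 without NHD13 marrow 1, 2 and 3. Of the lists, B cell markers (13 of 18, 15 adjusted over the list alone, camera adjusted p = 5.15e-10) and mast cell, basophil and eosinophil genes (8 of 11, adjusted p = 1.45e-05) were higher in CA10, and megakaryocyte and platelet genes were lower (10 of 11, adjusted p = 1.4e-06). Exocrine pancreas genes (4 of 7, adjusted p = 0.0295) and thymic epithelium genes (3 of 11 higher and 1 lower, 7 and 1 over the list alone, adjusted p = 0.0256) were higher too, with Prss2, a trypsinogen gene, at 1.45 ± 0.37. The adjusted p of these 5 lists was 0.298, 0.0504, 0.6, 0.647 and 0.6 with an estimated correlation. The other 7 lists that passed in the pooled fit, B cell precursor markers higher and the stem and progenitor, erythroid, stromal, mitotic, DNA replication and interferon lists lower, had 0.647 to 0.684 by that measure. In the blocked fit the stem and progenitor, thymic epithelium, exocrine pancreas and interferon lists no longer passed. Lists that passed in the blocked fit and not in the pooled one were the HOXA cluster, lower in CA10 with its direction turned, the HOXC cluster, also lower, and the neutrophil late granule, MHC class II and myeloid primary granule genes, all higher.

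In CA10 against wild-type thymus (n = 4 and 7) Hoxa9 stood at 5.42 ± 0.95 log2 units (SE, adjusted p = 0.79), with all 4 CA10 arrays above all 7 wild-type arrays, Meis1 at 2.18 ± 0.50, Hoxa10 at 1.85 ± 0.79, Hoxa7 at 1.04 ± 0.21, Hoxa5 at 0.86 ± 0.51 and Pbx3 at 0.12 ± 0.41. The HOXA cluster rose as a list (0 of 8, 2 adjusted over the list alone, camera adjusted p = 3.48e-06), and so did neutrophil late granule genes (0 of 15, 8 over the list alone, median 1.18, adjusted p = 5.47e-10), with S100a9 at 2.21 ± 0.68. These lists also passed with an estimated correlation (adjusted p = 0.0406 each). Erythroid genes (0 of 19, 2 over the list alone, adjusted p = 4.91e-05), stromal and vessel genes (0 of 17, adjusted p = 4.67e-05) and myeloid primary granule genes (0 of 9, 1 over the list alone, adjusted p = 0.00812) rose and T cell markers (0 of 17, adjusted p = 0.0309) fell, with adjusted p = 0.21, 0.657, 0.21 and 0.806 with an estimated correlation. limma called 0 genes, with 520 at an unadjusted p under 0.05, and 1 without CA10 thymus 3. Wild-type thymuses 2 and 6 and CA10 thymus 3 stood apart from their groups; without these 3, 6 genes were called, among them Hoxa9 at 6.61. The T cell list did not pass with the array set as a block or within the wide array set. Without the 3 thymuses the T cell list passed (camera adjusted p = 0.000126), HOX cofactors and megakaryocyte genes also rose, and mitotic and DNA replication genes fell.

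NHD13 thymus had higher Hoxa9 than wild type, by 5.03 ± 1.05 log2 units (SE, n = 3 and 7, adjusted p = 0.0403). The other Hoxa9 probe set differed less, at 7.54 ± 1.51 (SD) in NHD13 and 6.20 ± 0.55 in wild type. Pbx3 rose by 4.76 ± 0.45, Klhl4 by 4.37 ± 0.41, Fbp1, an enzyme gene of glucose synthesis, by 4.04 ± 0.53, Ddc, an enzyme gene of dopamine synthesis, by 3.79 ± 0.51, Olig3, a transcription factor gene of the nervous system, by 3.58 ± 0.40 and Hoxa7 by 2.18 ± 0.23. Hoxa10 at 1.94 ± 0.87, Meis1 at 0.30 ± 0.56 and Hoxa5 at 0.06 ± 0.56 were not called. The Hoxa5 value depends on the probe set, since the other one was at 8.58 ± 0.45 (SD) in NHD13 and 6.23 ± 1.09 in wild-type thymus, and the mean of probe sets gave 1.20, not called. Ms4a1 (−3.41 ± 0.68), Cd2 (−3.26 ± 0.48), Cd69, an activation marker of T cells (−3.22 ± 0.60), the lymphocyte GTPase genes Gimap6 (−2.93 ± 0.39) and Gimap8 (−2.73 ± 0.43), and Dgka (−2.69 ± 0.50) fell. The groups did not overlap for 116 of the 117 called genes, from which the largest rises and falls were taken by rule.

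The HOXC cluster rose in NHD13 thymus (3 of 5, 4 adjusted over the list alone, median 2.62, camera adjusted p = 1.81e-09, 0.0516 with an estimated correlation), with Hoxc4 at 3.16 ± 0.43, Hoxc8 at 2.64 ± 0.20 and Hoxc6 at 2.62 ± 0.30. The HOXA cluster (2 of 8, adjusted p = 0.00636), DNA replication genes (0 of 20, adjusted p = 7.93e-05) and mitotic genes (0 of 19, adjusted p = 0.0493) rose as lists. B cell markers (1 of 18, 8 over the list alone, adjusted p = 5.49e-08), T cell markers (1 of 17, 6 over the list alone, adjusted p = 9.56e-05) and immediate early genes (2 of 14, 4 over the list alone, adjusted p = 0.00636) fell, with Egr1 at −2.32 ± 0.44. None of these 6 lists passed with an estimated correlation (largest adjusted p = 0.794).

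limma called 117 genes in NHD13 against wild-type thymus, 61 higher and 56 lower. The count was 42 and 64 without NHD13 thymus 1 and 3, and 47, 317, 74, 53, 53, 199 and 44 without wild-type thymus 1 to 7. Within the wide array set, and with the array set as a block, 199 genes were called, the mitotic list did not pass, and Hoxa9 at 4.98 was not called. Without the 3 thymuses that stood apart, 1637 genes were called, Cd4 (−2.35) and Cd8b1 (−3.87) among them, and the mitotic list again did not pass. Neutrophil late granule, red pulp macrophage and stromal genes rose there.

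CA10 thymus against NHD13 thymus (n = 4 and 3) had higher Ighm, by 2.37 ± 0.37 log2 units (SE, adjusted p = 0.0169), Tesc by 1.97 ± 0.25, Bcl6 by 1.58 ± 0.27 and Tnfrsf4 by 1.12 ± 0.21. Klhl4 (−5.43 ± 0.46), Pbx3 (−4.65 ± 0.49), Fbp1 (−4.35 ± 0.59), Olig3 (−3.88 ± 0.44), Ddc (−3.76 ± 0.56) and Hoxc4 (−3.15 ± 0.47) were lower. The groups did not overlap for any of the 33 called genes, from which these 10 were taken. Meis1 stood at 1.88 ± 0.62, Hoxa5 at 0.79 ± 0.62, Hoxa9 at 0.39 ± 1.16, Hoxa10 at −0.09 ± 0.97 and Hoxa7 at −1.14 ± 0.25, none called. The HOXC cluster (3 of 5, camera adjusted p = 6.59e-07), DNA replication genes (0 of 20, adjusted p = 4.21e-07) and mitotic genes (0 of 19, adjusted p = 0.00804) were lower as lists. B cell markers (adjusted p = 0.000122), T cell markers (adjusted p = 0.0285), neutrophil late granule genes (adjusted p = 0.0031), immediate early genes (adjusted p = 0.00492) and megakaryocyte and platelet genes (adjusted p = 0.0083) were higher, with no member called over all genes and 2, 1, 0, 4 and 0 members adjusted over the list alone. With an estimated correlation the adjusted p was 0.165 for the HOXC cluster and 0.619 to 0.828 for the rest. limma called 33 genes, 4 higher and 29 lower; the count was 19 and 11 without CA10 thymus 1 and 2, 17 without NHD13 thymus 1, 86 with the array set as a block and 526 without the 3 thymuses. The T cell list did not pass with the block or within the wide set, and the mitotic and immediate early lists did not pass without the 3 thymuses, where B cell precursor markers were higher. Hoxa7 (−1.14) was called with the block.

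Whether a transgene's effect differed between tissues was tested directly. The NHD13 effect on Olig3 was 0.06 log2 units in lineage-negative marrow, −0.28 in whole marrow and 3.58 in thymus (limma F test, adjusted p = 1.62e-11), and that on Emx2 and Dlx1, homeobox genes of the brain, was 3.12 and 2.72 in thymus against −0.14 to 0.32 in both marrows (adjusted p = 1.18e-10 and 4.89e-06). The chemokine gene Ccl22 (−2.50 in thymus), Fbp1 (4.04) and Ptpn13 (1.80) followed, with adjusted p = 0.000302, 0.000305 and 0.00059. Hoxa7 differed as well (0.74, 0.51 and 2.18, adjusted p = 0.0247). In all 131 genes differed, and the count was 1472 without NHD13 lineage-negative marrow 2, 215 without NHD13 thymus 3, 79 without wild-type lineage-negative marrow 1 and 274 without wild-type thymus 2. For CA10 over 4 tissues the same limma test called 0 genes, with 415 at an unadjusted p under 0.05 and Syn2, Zfp446 and Slit2 at the smallest adjusted p, 0.511.

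Genes called in leukemic spleen overlapped between the transgenes. Against wild-type spleen 737 genes were higher in both and 281 lower in both, where independent lists would share 166 and 45.9, and 6 went opposite ways. Across genes, which are not independent replicates, the log2 changes correlated at 0.74 with a covariance of 0.403, against 0.75 and 0.097 for simulated unchanged groups with the same 2 controls. With 1 wild-type spleen as the control of each transgene, so that none was shared, the correlation was 0.59 and 0.66 and the covariance 0.35 and 0.38, so shared controls account for only part of the covariance. In these fits 0 and 1 genes were called for CA10, too few for an overlap. With CA10 spleen without clinical signs as the control of CA10 leukemia, 488 genes were higher in both and 154 lower in both, where independent lists would share 122 and 34.4, and 13 went opposite ways. There the correlation was 0.62 and the covariance 0.23. In thymus the correlation was 0.34 and the covariance 0.054, against 0.33 and 0.046 for unchanged groups, and 0.08 and 0.01 with the wild-type arrays split. That correlation was 0.18 to 0.49 when 1 array was left out, and −0.21 to 0.34 over the 70 splits. In lineage-negative marrow the correlation and covariance were 0.43 and 0.043 against 0.50 and 0.112, with correlations of 0.01 to 0.68 when 1 array was left out. In whole marrow they were −0.51 and −0.075 against 0.33 and 0.021, and −0.12 and −0.01 with each transgene set against wild-type marrows of its own array set.

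Over the 15 comparisons, 139 of 420 list tests passed and 6 held with an estimated correlation: the HOXA cluster in CA10 lineage-negative marrow and thymus, neutrophil late granule genes in CA10 thymus, B cell markers and mast cell, basophil and eosinophil genes in NHD13 whole marrow, and dendritic cell genes between the leukemias. No list that passed had a median or mean of the opposite sign. Red pulp macrophage genes passed in no comparison before alternatives, with the smallest adjusted p of 0.0945 in NHD13 thymus. The HOXD cluster and the fusion partner genes, with 3 measured genes each, were not tested. Their medians ranged from −0.18 to 0.30 and from −0.33 to 0.29. Of the fusion partners, Nup98 stood at 0.42 ± 0.20 in NHD13 leukemic against wild-type spleen and 0.09 ± 0.18 in NHD13 whole marrow, Hoxd13 at 0.13 ± 0.20 and −0.02 ± 0.18, and Mllt10, the mouse AF10 gene, at −0.21 ± 0.38 in CA10 leukemic against wild-type spleen, none called. With the mean of its probe sets Nup98 stood at 0.75 in NHD13 leukemic against wild-type spleen and was called. In CA10 leukemic against CA10 healthy spleen Nup98 fell on the probe set used (−0.53 ± 0.15, adjusted p = 0.0459), but its other probe set went the other way, with means of 7.33 and 6.79, and the mean of probe sets gave 0.01. Nup98 was lower in CA10 than in NHD13 leukemic spleen (−0.82 ± 0.14, adjusted p = 0.000653), also with the mean of probe sets (−0.51), but it stood at −0.35 and was not called with the C57B6 marrow difference subtracted. Whether these probe sets match the part kept in a transgene is not given in the sources used here, so they are no check of the genotype labels.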

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

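The tests on C57B6 marrow genes, spiked controls, array sets and thymus lists described here were chosen only after the result was seen, and so were the tests on other splits of the arrays.

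The NHD13 leukemic spleens had levels like those of the C57B6 marrows in most of 84 genes that set these marrows apart from the other wild-type marrows. Ms4a4b was at 8.01 ± 1.53 in them (SD, n = 6), 9.67 ± 0.36 in C57B6 marrow (n = 3) and at most 4.32 in the other 48 arrays, and Ifi202b was at 4.31 ± 0.39 and 4.31 ± 0.20 against 4.37 to 12.31 in the other 48, some of which lie within the C57B6 range. The NHD13 transgene without leukemia is argued against, since healthy NHD13 tissues had a median of 14.3 percent of these genes on the C57B6 side. A C57B6 background of the NHD13 leukemic mice may account for it, with 75.6 percent on that side. Separate labelling of these 9 arrays cannot be told apart from strain, since the spike ratio set the same arrays apart from the nearest other array by 0.35 log2 units.

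Many genes differed between CA10 and NHD13 whole marrow. Of the 4452 genes, 96.0 percent differed in the same direction between wild-type marrows of the array sets, so the array set may account for most of the count. The wild-type marrows of the narrow set were female and those of the wide set male, so this share cannot part array set from sex. The transgenic groups held both sexes, with 1 male and 2 female CA10 and 2 male and 1 female NHD13 marrows. For 4381 of the 4452 genes these groups did not overlap on any array, which argues against sex as the account of those genes. With the sets parted through the wild-type marrows 147 genes were called, and the median ratio of the difference within array sets to the pooled one was 0.25, which leaves open how far the transgenes differ in the other genes. Some genes, Ear3 (4.73) and Klhl4 (−3.41) among them, were called with the array set as a block as well, so the array set alone is a poor account of those.

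Wild-type thymus 2 and CA10 thymus 3 stood apart from the 5 other wild-type thymuses that served as reference. Mitotic genes were lower in them by a median of −4.03 and −2.36 log2 units and T cell markers by −2.58 and −2.22. Fewer thymocytes in an otherwise complete thymus are argued against, since thymic epithelium genes were lower too, by −2.84 and −2.00. Tissue from outside the thymus in the sample may account for it, with stromal and vessel genes higher by at least 1.80, and B cell markers by 2.25 and 0.52. Shrinkage of the thymus with age was not tested and stays open.

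Other splits of the same arrays into groups of the same sizes were fitted for each count. For CA10 leukemic against CA10 healthy spleen (920 genes), 1 of 100 splits, the real one, gave as many, and the highest other gave 548, which makes a chance split of these arrays an unlikely account. The same holds for CA10 against NHD13 leukemic spleen (3782; 1 of 100, highest other 716), NHD13 against wild-type thymus (117; 1 of 100, highest other 28, also within the array sets) and CA10 against NHD13 thymus (33; 1 of 35, highest other 3). Between the leukemias the real split also follows the spike ratio, at most 0.11 in NHD13 and at least 0.46 in CA10 leukemic spleen. That split thus cannot part leukemia type from labelling or strain. The real split is counted in each share, so these are the smallest shares the test can give. They were not adjusted over the counts tested, and the splits treat arrays as separate mice, which the labels do not say. For NHD13 against wild-type whole marrow (181) 3 of 84 splits, and for C57B6 against other wild-type marrow (2946) 2 of 84, gave as many. The highest others, 9524 and 9216, set wild-type marrows 4 to 6 apart and follow the array set, which within wild-type marrow is also the sex. Splits within the array sets number 20 in each, too few for a share under 0.05, with the highest others at 240 and 164. With the array set as a block these comparisons gave 355 genes and, within the wide set for C57B6, 1777. Where the real count is 0, every split gives as many and the share says nothing about chance. This holds for CA10 against wild-type whole marrow (84 of 84), where the highest, 9902, again followed the array set, with 1 gene in the blocked fit, and for CA10 against wild-type thymus (100 of 100), where the highest, 2189, set wild-type thymuses 2 and 6 and CA10 thymuses 3 and 4 apart. For the difference of the NHD13 effect between tissues (131), 10 of 100 gave as many, with the highest at 7969, so chance cannot be excluded. Splits that call many genes point to a structure of the samples. The 10 splits of 3 against 3 are too few for a share under 0.05: NHD13 against wild-type lineage-negative marrow gave 9 with the highest other at 0 (1 of 10), CA10 against wild type 0 with the highest other at 2 (10 of 10), CA10 against NHD13 lineage-negative marrow 0 and 0 (10 of 10), and CA10 against NHD13 whole marrow 4452 and 0 (1 of 10).

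A value far from the others of its group by the gap to its nearest neighbor was found in 55 of 577 groups of values, where chance gives about 5 percent, 1 in 20. Groups with fewer than 4 arrays were not examined. These were all lineage-negative marrows, the CA10, NHD13 and C57B6 whole marrows, NHD13 thymus and wild-type spleen, so their absence below says nothing about them. In wild-type thymus 2, Ngp (9.25), Bgn (10.15), Ms4a1 (10.53), Cd79a (10.04) and Fcrla (6.87) were high, and Cd69 (7.34), Cd4 (8.74), Cd8b1 (8.11), Aurkb (4.55), Cdk1 (6.03), Egr1 (8.30) and Egr2 (6.11) were low. Wild-type thymus 6 had low Pbx3 (4.29), high Hoxd13 (5.81) and Hoxc5 (5.69), and a low 75th percentile (7.03). In NHD13 leukemic spleen 3, Ctsg (9.47), Ifitm6 (7.96), Chil3 (10.23), Mndal (6.23), Ctss (9.63) and Btg2 (7.49) were low. NHD13 leukemic spleen 5 had high Cd4 (6.64), low Kif20a (8.45) and Mllt10 (7.54), and a high Gapdh 3' minus 5' signal (0.85). Cr2 (5.47) and Fcer2a (5.55) were high in NHD13 leukemic spleen 6, Kel (7.83) and Rhd (8.60) low in 2, and Mcm4 (11.33) high in 4. CA10 leukemic spleen 2 had high Ifi202b (12.31) and low Serpina1b (7.87) and H2-Aa (12.37), and spleen 3 had high Hoxa5 (8.07) and Hoxa7 (8.36) and low Hoxc5 (4.43). Cenpe (7.37), Kif11 (7.63), Cenpf (7.96), Prc1 (8.14) and Rrm1 (9.79) were low in CA10 leukemic spleen 4, and Pknox1 (8.18) and Bex6 (8.47) in 5. CA10 healthy spleen 3 had low Pbx3 (6.08), and CA10 healthy spleen 1 a high Gapdh 3' minus 5' signal (2.09). In wild-type whole marrow, Hoxd13 (5.65) was high and Ighm (12.83) and Mmp9 (10.51) low in 4, Gzma (7.44) high in 6, Klre1 (5.12) high in 1 and Ccnb2 (11.70) high in 3. Car1 (5.73) was high in CA10 thymus 1, Hoxa5 (7.64) low in 2 and Cd177 (6.21) high in 3.

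The effect of NHD13 differed between lineage-negative marrow, whole marrow and thymus by the F test for Olig3 (adjusted p = 1.62e-11), Emx2 (1.18e-10), Dlx1 (4.89e-06), Ccl22 (0.000302), Fbp1 (0.000305), Ptpn13 (0.00059) and Hoxa7 (0.0247).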

How the results depend on the processing

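The alternatives for array sets, thymuses, RNA quality, unshared spleen controls and the C57B6 difference were chosen after seeing the data. Under the alternatives other than leaving out 1 array, 121 counts or correlations stayed close to the value reported, counts within 1.5 times, and 60 did not. For named genes, 6931 of 7515 values kept their side of the threshold (109 of these, never called, changed sign), 379 were no longer called, 194 became called and 11, called in either fit, reversed; with 1 array left out these were 6398 (82), 523, 66 and 0 of 6987. Except where a value or a smaller set of arrays shows it, the cause was not tested. Weak signals limit what the arrays resolve over background.

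Counts of genes that moved follow. With all 57 arrays in 1 model, CA10 leukemic spleen gave 460 against CA10 healthy and 691 against wild type, NHD13 leukemic spleen 3046, the leukemias against each other 2267, NHD13 lineage-negative marrow 43, CA10 against NHD13 lineage-negative marrow 9, CA10 whole marrow 7, NHD13 whole marrow 45, CA10 against NHD13 whole marrow 2609, CA10 thymus 1, NHD13 thymus 543, CA10 against NHD13 thymus 217 and C57B6 marrow 1612. With only the groups compared, CA10 leukemic against wild-type spleen gave 2199, CA10 lineage-negative marrow 2, NHD13 lineage-negative marrow 0, NHD13 whole marrow 85, CA10 against NHD13 whole marrow 8375, CA10 against NHD13 thymus 2 and C57B6 marrow 1625. With the C57B6 difference subtracted, NHD13 leukemic spleen gave 2512 and the leukemias against each other 1452. Quantile normalization gave 0 in NHD13 lineage-negative marrow, 9 in CA10 whole marrow, 230 in NHD13 thymus, 205 for the NHD13 tissue difference and −0.44 for the whole marrow correlation. With unshared wild-type spleens the leukemic spleen correlation was 0.59 and 0.66. The array set as a block gave 37 in NHD13 and 5 in CA10 against NHD13 lineage-negative marrow, 1 in CA10, 355 in NHD13 and 147 in CA10 against NHD13 whole marrow, 199 in NHD13 and 86 in CA10 against NHD13 thymus, and 279 for the NHD13 tissue difference. Within the wide set these were 21 and 2 in lineage-negative marrow, 199 and 86 in thymus and 1777 in C57B6 marrow. In CA10 whole marrow the mean of probe sets gave 1, trend and robust settings 3, the narrow set 6 and the C57B6 control 6442, which gave 2466 in NHD13 whole marrow. Without the 3 thymuses, CA10 thymus gave 6, NHD13 thymus 1637, CA10 against NHD13 thymus 526, and the tissue differences 2 for CA10 and 360 for NHD13. List tests that passed numbered 6 with an estimated correlation.

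With the replicate block NHD13 lineage-negative marrow gave 15 genes, CA10 against NHD13 lineage-negative marrow 1, CA10 whole marrow 8235, CA10 against NHD13 whole marrow 8097, NHD13 thymus 1, CA10 against NHD13 thymus 2 and C57B6 marrow 1849. It changed no other count by more than 1.5 times (744 for CA10 leukemic against CA10 healthy spleen, 1497 for CA10 and 4343 for NHD13 leukemic against wild type, 3479 between the leukemias, 0 in CA10 healthy spleen, 0 in CA10 lineage-negative marrow, 233 in NHD13 whole marrow and 0 in CA10 thymus), and 132 list tests passed. In whole marrow the numbers 4 to 6 occur only in wild type. The block therefore set the CA10 marrows, all narrow, against wild-type marrows 1 to 3, all wide, so the 8235 genes compare array sets as well. Outside lineage-negative marrow pairs correlated from −0.57 to 0.74, and no comparison with 3 or more pairs had all of them above 0.1. With 3 or more pairs, not every array correlated best with its own number in any comparison, lineage-negative marrow included. In CA10 leukemic against wild-type spleen both pairs did, at 0.12 and 0.21.

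With 1 array left out, counts ranged from 127 to 1413 for CA10 leukemic against CA10 healthy spleen, 0 to 1351 for CA10 leukemic and 2149 to 5021 for NHD13 leukemic against wild type, 2995 to 3892 between the leukemias, 0 to 0 for CA10 healthy spleen, 0 to 0, 0 to 31 and 0 to 5 in lineage-negative marrow, 0 to 13, 93 to 278 and 124 to 2801 in whole marrow, 0 to 1, 42 to 317 and 11 to 35 in thymus (CA10, NHD13 and CA10 against NHD13 each), 1534 to 4271 for C57B6 marrow, and 0 to 0 and 79 to 1472 for the tissue differences of CA10 and NHD13. A spleen group left with 1 wild-type array is assumed to vary like the other groups.

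Values called in either fit that reversed were Nup98 in CA10 leukemic against CA10 healthy spleen (0.01) and Rrm1 between the leukemias (0.02) with the mean of probe sets, and Hoxa5 in NHD13 whole marrow (1.26) likewise. With the C57B6 difference subtracted, Itgb2l (−0.03) and Klra8 (−1.03) reversed in NHD13 leukemic spleen, and Ms4a4b (1.68), Mndal (1.76) and Klra8 (0.90) between the leukemias. With the C57B6 control Ppbp (0.58) and Pf4 (0.65) reversed in CA10 whole marrow, and with the array set as a block Cel (−0.02) between the whole marrows. DNA replication genes were lower without NHD13 lineage-negative marrow 3 in CA10 against NHD13 lineage-negative marrow (adjusted p = 0.0437), and higher in CA10 whole marrow with the C57B6 control (adjusted p = 0.00464).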

Other observations

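No tests were made on the values here, and the probe set was looked up only after the result was seen. Hoxa5, a HOX gene of the same cluster as Hoxa9, has more than 1 probe set, and the values reported came from the one with the highest mean. On its other probe set the signal was 8.17 ± 0.12 (SD, n = 3) in NHD13 whole marrow, 5.48 ± 0.28 (n = 6) in wild-type whole marrow, 5.96 ± 0.41 (n = 3) in CA10 whole marrow and 6.09 ± 0.31 (n = 3) in C57B6 marrow. In lineage-negative marrow it was 7.34 ± 0.13 (n = 3) in CA10, 7.31 ± 0.19 (n = 3) in NHD13 and 5.64 ± 0.14 (n = 3) in wild type. In thymus it was 8.78 ± 0.83 (n = 4) in CA10, 8.58 ± 0.45 (n = 3) in NHD13 and 6.23 ± 1.09 (n = 7) in wild type. In spleen it was 7.26 ± 1.29 (n = 6) in CA10 leukemia, 8.28 ± 0.65 (n = 6) in NHD13 leukemia, 7.29 ± 0.34 (n = 5) in CA10 without clinical signs and 5.80 ± 0.19 (n = 2) in wild type. The other Hoxa9 probe set was at 7.86 ± 0.99 in CA10 and 6.20 ± 0.55 in wild-type thymus. It was at 7.75 ± 0.08 in CA10 and 6.92 ± 0.54 in wild-type whole marrow.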
